A study of Mus musculus with 4 samples.

How the data were processed

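Polyadenylated RNA was profiled by single-end sequencing of 4 libraries from cultures of dissociated dorsal root ganglion (DRG) neurons of day 13.5 mouse embryos. Per the labels' protocols, the cultures grew with nerve growth factor and with fluorodeoxyuridine plus uridine, which act against dividing cells, and lentivirus was added on day 2 in vitro. The labels also give day 5 in vitro for replating. Per the same labels, RNA over 200 nt was taken, and the libraries were prepared with a Lexogen SENSE kit and read to a length of 50 nt. The samples were grouped by the titles and the lentivirus label into 2 control libraries (pLKO virus) and 2 PROM1 libraries (virus carrying human PROM1, also called CD133). The series text describes both conditions as biological duplicates.

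The submitters' processing notes name CASAVA, TopHat2 and the mouse build mm9. The annotation and the use of strand are not given in the sources used here. The deposited table holds 1 row for each of 14236 RefSeq transcripts, of which 13405 have mRNA accessions and 831 have non-coding RNA accessions. Its name restricts it to transcripts of status OK, so a gene total here covers the listed transcripts alone. Per the file headers, the authors computed an FPKM (fragments scaled by transcript length and by the mapped total) for each library with Cufflinks. Per the file headers, they also deposited 1 FPKM per group, and these group values are not the means of the library values. The deposited p-values and q-values, with a mark for significance, belong to the authors' comparison of the 2 groups. Its tool is not given in the sources used here. A deposited log2 ratio is written as a very large number for the 378 transcripts with a group value of 0, and a second deposited log2 column was found to equal the ratio of the group FPKM values after adding 0.1 to each, in all 14236 rows (within 1e-06). The −log10 column in the deposited table repeats the p-values. All 4 columns of library values were mapped to samples by name.

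FPKM values carry no read counts. Low values of transcripts without annotated isoforms were searched for steps of whole reads. Between any pair of libraries no log2 ratio, rounded to 0.01, was shared by more than 2.18% of 190 to 290 such transcripts, so no steps were found and the depth is unknown. No counting interval or count test was used.

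Symbols came from the descriptions in the deposited table for 13996 transcripts. The other 240 transcripts had none and were named by accession through a RefSeq table of assembly GRCm38.p6. In the deposited symbol column, 33 symbols had turned into calendar dates, so that column was not used. Coordinates are not printed, since the reference at hand is of another build than mm9. Transcripts with a missing value in any library (39) were left out, and the FPKM of the remaining transcripts was summed per symbol. This gave 11258 genes, of which 2146 had more than 1 listed transcript. Sums were used because Cufflinks divides the reads of 1 gene among its isoforms, so that isoform values depend on that division.

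Genes with a mean of at least 1 FPKM over the 4 libraries were tested with limma 3.58.1 (R 4.3.3), with a trend of variance on level, on log2(FPKM + 1). All fold changes given without another source, and the counts of higher and lower members of a list, are on that scale, which understates the change of low genes. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. No exact permutation test of 2 libraries against 2 can give a two-sided p under 0.333. A total of 24 gene lists and the rule for naming genes were fixed before the data were examined. The 21 lists with at least 3 tested members were tested with camera at its preset correlation, with camera at an estimated correlation, and with fry, each adjusted over the 21 lists. Tested members were 20 of 20 for cholesterol synthesis and 12 of 12 for fatty acid synthesis. Coverage was lower for immediate early genes (6 of 11), glia (5 of 13), fibroblasts (3 of 11) and Smad targets (7 of 16). It was also lower for interferon (4 of 14) and cell cycle genes (5 of 16). A list result covers the tested members alone. Each list median was also placed among the medians of 10000 random lists matched on level in 20 bins. The subject of the cholesterol, fatty acid and Smad lists was chosen with knowledge of the study's published theme, while their members are textbook members.

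The rule named the genes past the threshold by limma or with a deposited q under 0.05, with at least 1 FPKM in the higher group and with both PROM1 libraries on 1 side of both control libraries, up to 12 in each direction. It added every member of the cholesterol synthesis list, the mouse prominin genes, and up to 4 members of each other list with the largest absolute change. Under it 117 genes were named, some of which are not reported here. Mouse Prom1 and Prom2 and the human PROM1 transgene were not analysed here, so overexpression was not checked against the labels.

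The steps were tested on simulated data with the levels and residual spread of the 10108 tested genes. Of 200 genes changed by 1 on the log2 scale, 0 were called, and likewise 0 of 200 changed by 2. Of 200 changed by 3, 145 were called, together with 5 unchanged genes, in a run on 10107 genes. A shift of -0.8 put into the cholesterol list was recovered as a median of -0.76 to -0.82, with a camera adjusted p of 8.6e-15 or lower at the preset correlation. With an estimated correlation the same shift gave adjusted p = 0.211 to 0.261 and was missed. In 20 simulated runs with no change, 0 lists and 0 genes were called. The simulated noise was drawn for each gene independently. These runs therefore cannot show how correlation among list members affects the camera calls at the preset correlation.

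The alternatives were other pseudocounts, other filters on level, rescaling by the median of ratios, the replicate number as a block, and leaving out each library. Chosen after seeing the data were a fit per transcript, a fit without records under 200 nt, and a fit on genes with 1 listed transcript. Figures were drawn with matplotlib 3.10.9.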

Results

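The data describe how the transcriptome of cultured embryonic DRG sensory neurons differed when human PROM1 was supplied by lentivirus. PROM1, or prominin 1, is a membrane glycoprotein of cell protrusions that binds cholesterol and is widely used as a stem cell marker. The comparison had 2 control libraries and 2 PROM1 libraries, grouped by their labels. The level of PROM1 itself was not analysed here, so its overexpression was not checked. Library FPKM values summed to 361232 and 385963 in control libraries 1 and 2, and to 357805 and 379596 in PROM1 libraries 1 and 2. Control library 2 and PROM1 library 2 held more transcripts listed at exactly 0 (283 and 237) than control library 1 and PROM1 library 1 (89 and 121). Pearson's r between libraries, across genes on the log2 scale, was 0.92 for the control pair and 0.92 for the PROM1 pair, and it was highest, at 0.95, between control library 1 and PROM1 library 1. Genes are not independent replicates, so these values describe the libraries.

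Single genes past the threshold were few. The authors' deposited table marked 29 transcripts as significant, with q up to 0.0982, and 18 of them had q under 0.05. Of the 29, 6 were listed at 0 in the control group, 8 were listed at 0 in the PROM1 group, and 15 had values in both groups. Of these 15, 10 were higher and 5 lower in PROM1 cultures in the authors' deposited table. The higher transcripts in the authors' deposited table included Cxxc5, a zinc finger regulator of Wnt and BMP signalling, at 8.80 against 30.7 FPKM (3.48-fold). The kinase-like protein Trib1 was at 8.30 against 21.9 FPKM (2.63-fold), and Pidd1, a death-domain protein induced by p53, was at 38.9 against 100.3 FPKM (2.58-fold), in the authors' deposited table. F2r, the thrombin receptor, was 2.04-fold higher, St8sia2, a polysialyltransferase acting on NCAM, 2.08-fold higher and the copine Cpne2 2.11-fold higher in the authors' deposited table. The lower transcripts in the authors' deposited table included the cholesterol synthesis enzymes Nsdhl (2.41-fold, 114.0 against 47.2 FPKM) and Sqle (1.97-fold, 136.1 against 68.9 FPKM) at q = 0.0395, and Lss (1.94-fold) at q = 0.0821. Gpr162, an orphan receptor, was 2.91-fold lower at q = 0.0395 (10.4 against 3.57 FPKM) in the authors' deposited table. Its group values lie above its library values, which were 3.63 and 4.41 FPKM in control and 2.92 and 1.27 FPKM in PROM1. The libraries therefore do not bear out the size of that fold. The prolactin receptor Prlr was 3.10-fold lower at q = 0.0647 in the authors' deposited table. Prlr and Synj1 fall outside the rule for naming genes and were chosen after their values were seen. The increase of 1 Synj1 transcript in the authors' deposited table (8.13 against 28.0 FPKM, q = 0.0647) concerned 1 isoform of that gene.

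Library values are given here for genes that the rule named through the threshold, which by that part of the rule had both PROM1 libraries on 1 side of both control libraries. Cxxc5 rose from 6.86 and 10.8 FPKM in the control libraries to 28.4 and 28.8 FPKM in the PROM1 libraries by the deposited call, a log2 change of 1.62 ± 0.27 (SE). Pidd1 stood at 46.6 and 44.6 FPKM against 132.3 and 113.2 FPKM, a log2 change of 1.41 ± 0.19 (SE), and Trib1 at 5.66 and 9.54 FPKM against 20.5 and 20.3 FPKM. The log2 changes of St8sia2, F2r and Cpne2 were 1.02 ± 0.24, 0.98 ± 0.28 and 0.97 ± 0.29 (SE). F2r had 60.3 and 36.6 FPKM and Cpne2 112.5 and 65.9 FPKM in PROM1 libraries 1 and 2, and without PROM1 library 1 their log2 changes were 0.63 and 0.58. Gpr162, at 3.63 and 4.41 against 2.92 and 1.27 FPKM, had a log2 change of -0.75 ± 0.37 (SE), which was -1.14 without PROM1 library 1 and -0.35 without PROM1 library 2. The following genes named in the same way were near the floor of detection. Smim9 and the protease gene Ctrl were listed at 0 in both control libraries and at 1.39 and 4.56 FPKM and at 0.672 and 5.11 FPKM in the PROM1 libraries, and Gm9079 was listed at 0, 0, 0.431 and 2.08 FPKM. Nudt1, Snhg4, Sbsn, Spata9 and Tipin were listed at 0 in both PROM1 libraries, at 0.0641 to 0.602 FPKM in control library 1, and at 2.37 to 3.49 FPKM in control library 2. The log2 change of Ctrl was 1.68, or 2.61 without PROM1 library 1, and that of Nudt1 was -1.42, or -2.17 without control library 1. Of 108 named genes followed without each library in turn, 68 had a log2 change that moved by over 1.5 times.

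In the limma fit to library values, 2 of 10108 tested genes had an adjusted p under 0.05 (limma), both lower in PROM1 cultures, and 475 genes had an unadjusted p under 0.05, where chance gives 505.4. Both were records of microRNA precursors shorter than 200 nt, Mir6945 (1579 and 928.1 FPKM in the control libraries, listed at 0 in both PROM1 libraries, limma adjusted p = 0.00133) and Mir3470b (42.8 and 50.9 FPKM, listed at 0 in both PROM1 libraries, limma adjusted p = 0.00638). Without records under 200 nt, 0 genes were called by limma, and 510 had an unadjusted p under 0.05. The calls changed when each library was left out in turn, and most of them were again on microRNA and other small RNA records. Mir3470b was no longer called by limma without control library 1 (log2 change -5.70, adjusted p = 0.194), control library 2 (-5.45, adjusted p = 0.1004) or PROM1 library 1 (-5.58, adjusted p = 0.0630), where its log2 change with all 4 libraries was -5.58. Its limma adjusted p over 11 alternatives ran from 0.00539 to 0.194, and that of Mir6945, called in all 11 of its alternatives, from 0.000383 to 0.0300. The fit per transcript is not among these 11, and it called 0 transcripts (limma), so neither record was called there. Both PROM1 libraries lay above both control libraries for 1668 genes (16.5%) and below them for 1770 genes (17.5%), where chance gives 16.7% for each.

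The genes of cholesterol synthesis were lower as a group in PROM1 cultures. Of the 20 enzymes from acetyl-CoA to cholesterol, all of which were tested, 19 had a lower mean on the log2(FPKM + 1) scale, and the list median was -0.76 on that scale, or 1.69-fold lower. Adjusted over the list alone, 12 of the 20 fell and 0 rose, while over all genes tested 0 passed (limma). The choice of this pathway followed the study's theme. The count adjusted over the list alone, the camera and fry p-values and the rank among random lists all rest on this choice. They are therefore not independent evidence of its direction. Both PROM1 libraries lay below both control libraries for 16 of the 20 enzymes, and above them for 0. Camera gave an adjusted p of 4.5e-15 at its preset correlation, and fry gave an adjusted p of 0.0246. With an estimated correlation, which was -0.0465 for this list, camera gave p = 0.0122 unadjusted and adjusted p = 0.256. That version also missed the simulated shift of -0.8, where noise was independent between genes. Its adjusted p therefore does not show that correlated members made the call at the preset correlation. The list median lay below all of 10000 random lists matched on level, whose central 95% ran from -0.18 to 0.12. In pairs of libraries with the same number, it was -0.83 for number 1 and -0.65 for number 2. Leaving out each library in turn left it between -0.80 and -0.70.

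Among the enzymes, Nsdhl, a sterol dehydrogenase that acts in C4 demethylation, fell from 102.0 and 91.6 FPKM in the control libraries to 47.7 and 30.8 FPKM in the PROM1 libraries, a log2 change of -1.31 ± 0.26 (SE). Mvd, the mevalonate diphosphate decarboxylase, fell from 14.2 ± 0.517 to 5.75 ± 1.02 FPKM (SD, n = 2), and Idi1, which isomerises the resulting isopentenyl unit, fell from 10.4 ± 1.82 to 4.19 ± 0.252 FPKM (SD, n = 2). Sqle, the squalene epoxidase, fell from 108.1 ± 21.9 to 52.3 ± 1.72 FPKM (SD, n = 2). The farnesyl diphosphate synthase Fdps fell from 67.1 ± 21.2 to 30.4 ± 0.252 FPKM (SD, n = 2), and Hmgcs1, which makes HMG-CoA, fell from 28.3 ± 4.03 to 13.6 ± 2.98 FPKM (SD, n = 2). The log2 changes of the remaining members that fell, adjusted over the list alone, were -0.85 for Lss, -0.82 for Msmo1, -0.78 for Acat2, -0.77 for Tm7sf2, -0.75 for Dhcr7 and -0.68 for Mvk. Tm7sf2 was at -0.45 without control library 1. Among the members that did not pass were Cyp51 (log2 change -0.56), Sc5d (-0.52), Fdft1 (-0.42), Hsd17b7 (-0.38), Ebp (-0.30) and Pmvk (0.20).

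**Figure D1:**
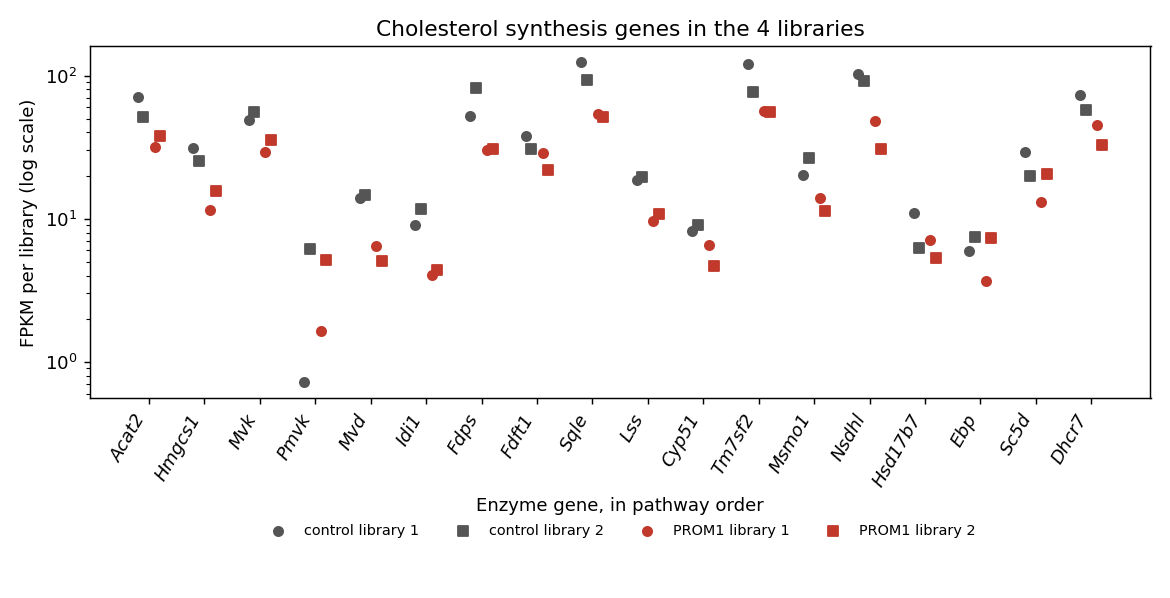
FPKM of 18 of the cholesterol synthesis genes (horizontal axis, in pathway order) in each of the 4 libraries, on a logarithmic vertical axis, with control libraries in grey, PROM1 libraries in red, circles for number 1 and squares for number 2. For 14 of the 18 genes drawn both red points lie below both grey points, and the exceptions are Pmvk, Hsd17b7, Ebp and Sc5d.

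Genes of sterol uptake and sensing and of fatty acid synthesis were also lower as lists. Among 11 tested genes of sterol uptake and sensing, 8 were lower and 3 higher, and 2 fell when adjusted over the list alone, among them Insig1, while 0 passed over all genes (limma). Insig1, which retains the sterol sensor in the endoplasmic reticulum, went from 13.7 ± 2.67 to 5.32 ± 0.514 FPKM (SD, n = 2). Lrp8, the gene of a reelin and lipoprotein receptor, had 6.59 and 7.02 FPKM against 0.150 and 3.02 FPKM. This value came from a non-coding RNA accession alone, so it does not describe the transcript that codes for the receptor. The log2 change of Lrp8 was -1.86, or -0.96 without PROM1 library 1. Stard4, a sterol carrier, had a log2 change of -0.66 ± 0.33 (SE). The list median was -0.28, with a camera adjusted p of 0.00835 and adjusted p = 0.519 with an estimated correlation. The camera call was lost without control library 1 (median -0.36, adjusted p = 0.137) and without PROM1 library 1 (median -0.17, adjusted p = 0.314). It was also lost with a mean level of at least 5 (median -0.28, adjusted p = 0.0938) and on genes with 1 listed transcript (median -0.27, adjusted p = 0.199), and its adjusted p over 13 alternatives ran from 0.00039 to 0.314.

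All 12 fatty acid synthesis genes had lower means in PROM1 cultures, with a median log2 change of -0.46 (1.37-fold lower), and 9 had both PROM1 libraries below both control libraries. None passed by itself, either adjusted over the list alone or over all genes (limma), and 3 had an unadjusted p under 0.05. The desaturases Fads2, Scd1 and Scd2 had log2 changes of -0.79 ± 0.28, -0.75 ± 0.23 and -0.60 ± 0.20 (SE), and the acyl-CoA synthetase Acsl3 of -0.57 ± 0.32 (SE). Camera gave an adjusted p of 3.8e-06 and adjusted p = 0.519 with an estimated correlation. The subject of this list was also chosen with knowledge of the study's theme, so these p-values are not independent evidence of its direction. The call held without each library in turn, with a median between -0.53 and -0.42. Of the 6 tested genes of cholesterol efflux and storage, 3 were higher and 3 lower, and 0 passed (camera adjusted p = 0.940). Apod, a lipocalin carrier, had a log2 change of -0.70 ± 0.30 (SE) and Nr1h2, an oxysterol receptor, of -0.19 ± 0.23 (SE). Abcg1, a sterol exporter, had 4.33 and 4.22 FPKM against 3.24 and 7.69 FPKM. The only Apoe transcript counted here was at most 3.28 FPKM in any library, which does not give the level of Apoe over all its transcripts.

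Markers of other cell types were compared in the same libraries. The 5 tested markers of Schwann cells and satellite glia, themselves cells that make cholesterol, all had lower means, with a median of -0.16, a camera adjusted p of 0.360 and a fry adjusted p of 0.0246. Without control library 1 this median was -0.36. The myelin protein gene Pmp22 had 36.9 ± 11.4 against 19.8 ± 1.35 FPKM (SD, n = 2), a log2 change of -0.83 ± 0.27 (SE), while Mbp had -0.20 ± 0.21, S100b -0.15 ± 0.40 and Gjc3 -0.16 ± 0.38 (SE). The 3 tested fibroblast markers were higher, with a median of 0.91, a camera adjusted p of 0.0181 and adjusted p = 0.519 with an estimated correlation. Col1a1, a fibrillar collagen chain, rose when adjusted over the list alone, from 0.545 and 1.24 FPKM to 3.33 and 4.28 FPKM, while 0 of the 3 passed over all genes (limma). Col1a2 stood at 0.302 and 0.694 against 1.32 and 2.34 FPKM, and Fbln1 had a log2 change of 0.17 ± 0.35 (SE). The fibroblast call was lost without control library 1 (median 0.72, adjusted p = 0.192) and without PROM1 library 1 (median 1.17, adjusted p = 0.137), and its adjusted p over 11 alternatives ran from 0.00741 to 0.192. The fibroblast median was 1.72 with a pseudocount of 0.1 and 0.58 with no filter on level. Of the macrophage list C1qb alone was tested, with 2.30 and 3.51 against 0.339 and 1.16 FPKM, and of the endothelial and pericyte list Acta2 alone, with a log2 change of -0.50 ± 0.37 (SE). The 4 tested globin genes did not pass as a list (median -0.20, camera adjusted p = 0.940). The embryonic Hba-x and Hbb-y had log2 changes of 0.63 ± 0.19 and -0.19 ± 0.60 (SE). The adult Hba-a1 (log2 change -0.21) and Hbb-b1 (-0.58) have near-identical copies that can share reads, so their values are uncertain.

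The lists for TGF-β and BMP signalling did not pass in the unpaired fit. Of 17 tested ligands, receptors and Smads 10 were higher and 7 lower, with a median of 0.12 (0.0304 without control library 1 and 0.23 without PROM1 library 2) and a camera adjusted p of 0.376. Smad9, a BMP-responsive Smad, had 4.59 ± 0.742 FPKM in control and 7.76 ± 0.904 FPKM in PROM1 cultures (SD, n = 2), and the type I receptor Bmpr1a had a log2 change of 0.65 ± 0.36 (SE), which was 0.21 without control library 1. Fst, which sequesters activin, had a log2 change of 0.66 ± 0.39 (SE) and Tgfb1 of 0.50 ± 0.45 (SE). Tgfb1 was at 0.11 without control library 1 and at 0.89 without control library 2. Of 7 tested Smad target genes, from a list of 16, 6 were higher, with a median of 0.21. None passed, adjusted over the list alone or over all genes (limma). Their list had a camera adjusted p of 0.175 and adjusted p = 0.766 with an estimated correlation. This list was called by camera without control library 2 (median 0.18, adjusted p = 0.00741) and without PROM1 library 2 (median 0.66, adjusted p = 0.0121), and its median was -0.15 without PROM1 library 1 (adjusted p = 0.920). Its adjusted p over 13 alternatives ran from 0.00741 to 0.920. Id3, an inhibitor of basic helix-loop-helix factors induced by BMP, was listed at 0.824 and 11.8 FPKM in the control libraries against 18.8 and 36.1 FPKM in the PROM1 libraries, and Id1 at 1.55 and 8.53 against 9.29 and 10.3 FPKM. On the log2 scale, the control libraries of both genes lay further apart than the PROM1 libraries did. Tgif1 and Pmepa1 had log2 changes of 0.29 ± 0.41 and -0.21 ± 0.41 (SE).

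Immediate early genes were higher as a list. All 6 tested members were higher, 5 with both PROM1 libraries above both control libraries, and the median log2 change was 0.78 (1.71-fold higher). Egr1, a zinc finger transcription factor, rose when adjusted over the list alone, from 0.312 and 1.37 FPKM to 4.16 and 5.03 FPKM, while 0 of the 6 passed over all genes (limma). Fos had 0.858 and 1.78 FPKM against 6.08 and 3.22 FPKM, Arc 2.77 and 6.09 against 10.96 and 6.46 FPKM, and Ier2 3.67 and 2.62 against 7.84 and 3.92 FPKM. Camera gave an adjusted p of 0.00031 and adjusted p = 0.519 with an estimated correlation. The call was lost without PROM1 library 1 (median 0.56, adjusted p = 0.123), and its adjusted p over 12 alternatives ran from 3.5e-05 to 0.123. The fibroblast markers above moved in the same direction in the same libraries.

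**Figure D2:**
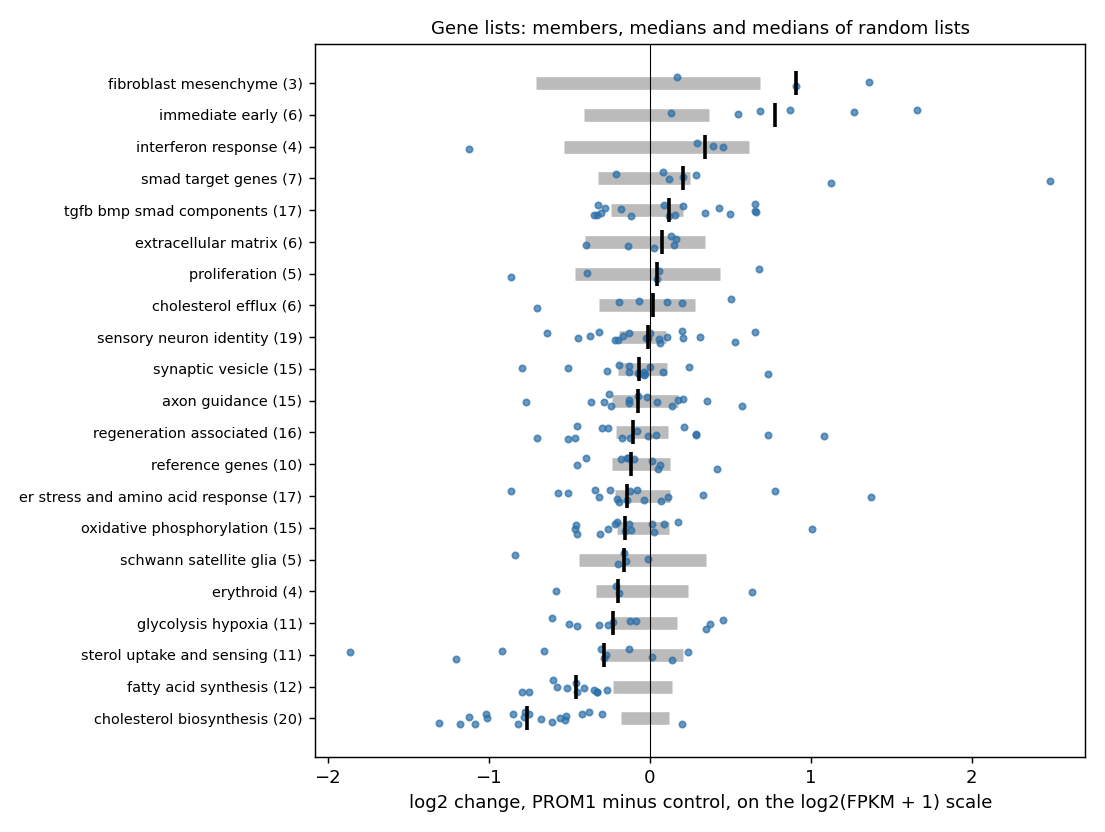
Log2 change between PROM1 and control cultures (horizontal axis, log2(FPKM + 1) scale) for the tested members of the 21 lists (rows, number of tested members in brackets), with blue points for genes, black ticks for list medians and grey bars for the central 95% of medians of random lists matched on level. The cholesterol synthesis median of -0.76, the fatty acid median of -0.46 and the sterol uptake and sensing median of -0.28 lie below their grey bars, and the immediate early median of 0.78 and the fibroblast median of 0.91 lie above theirs.

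Neuronal gene groups did not pass. Of 16 tested genes that sensory neurons induce after axon injury, 6 were higher and 10 lower (median -0.10, camera adjusted p = 0.780). Gadd45a was at 1.49 FPKM and listed at 0 in the control libraries, against 2.26 and 2.44 FPKM in the PROM1 libraries. Sema6a, a transmembrane semaphorin, had a log2 change of 0.73 ± 0.26 (SE), the stathmin Stmn4 of -0.70 ± 0.28 (SE) and the heat shock protein gene Hspb1 of -0.51 ± 0.27 (SE). The fry test in either direction gave this list an unadjusted p of 0.00815 and an adjusted p of 0.0571. Of 19 sensory neuron markers 9 were higher and 10 lower (median -0.01, or 0.0103 after rescaling by the median of ratios, camera adjusted p = 0.979). Nefh, the heavy neurofilament chain, had 381.0 ± 56.4 against 547.9 ± 22.8 FPKM (SD, n = 2), and Tac1, the precursor of substance P, 177.9 ± 56.0 against 112.9 ± 29.5 FPKM (SD, n = 2). Calca, the precursor of calcitonin gene-related peptide, had a log2 change of 0.66 ± 0.41 (SE), which was 0.0605 without control library 1, and Trpv1, the capsaicin receptor, of -0.45 ± 0.46 (SE). Of 15 presynaptic genes 4 were higher and 11 lower (camera adjusted p = 0.780), with log2 changes of -0.79 ± 0.31 for Syn2, 0.73 ± 0.21 for the glutamate transporter gene Slc17a7, -0.51 ± 0.24 for Sv2a and -0.27 ± 0.35 for Vamp2 (SE). Of 15 axon guidance genes 6 were higher and 9 lower (camera adjusted p = 0.940), with -0.77 ± 0.34 for Plxna4, 0.57 ± 0.29 for Plxna1, -0.37 ± 0.28 for Robo2 and 0.36 ± 0.42 for Efnb2 (SE).

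Stress and metabolic lists did not pass either. Of 17 genes of the endoplasmic reticulum stress and amino acid response 5 were higher and 12 lower (median -0.14, camera adjusted p = 0.507). Ddit3, a stress-induced transcription factor, had 15.6 ± 5.60 against 41.2 ± 6.64 FPKM (SD, n = 2), a log2 change of 1.37 ± 0.30 (SE), and did not pass over the list alone or over all genes (limma). Sesn2, a stress-induced regulator of growth signalling, had a log2 change of 0.78 ± 0.28 (SE), the chaperone gene Pdia4 of -0.57 ± 0.25 (SE) and the cystine transporter gene Slc7a11 of -0.86 ± 0.53 (SE), which was -0.0512 without PROM1 library 2. Of 11 glycolysis and hypoxia genes 3 were higher and 8 lower (camera adjusted p = 0.7004), with log2 changes of -0.61 ± 0.21 for Egln3, -0.50 ± 0.48 for Pdk1, 0.46 ± 0.34 for Pfkl and -0.45 ± 0.88 for Eno1 (SE). Of 15 genes of oxidative phosphorylation 5 were higher and 10 lower (camera adjusted p = 0.507), with 1.00 ± 0.49 for Cox6c, -0.46 ± 0.46 for Sdhb, -0.46 ± 0.33 for Uqcrc2 and -0.45 ± 0.27 for Sdha (SE). Cox6c was at 0.30 without control library 1 and at 1.71 without control library 2. The list of interferon genes, 4 of which were tested, did not pass (camera adjusted p = 0.780), and Isg15, Oasl2 and Ddx58 had group means from 0.836 to 1.52 FPKM. The 5 tested cell cycle genes did not pass (camera adjusted p = 0.940), with log2 changes of -0.86 ± 0.50 for Aurka, 0.68 ± 0.44 for Pcna, -0.39 ± 0.30 for Mcm2 and 0.06 ± 0.30 for Tyms (SE). Pcna was at 0.0906 without control library 1 and at 1.27 without control library 2. The 6 tested basement membrane and matrix genes did not pass (camera adjusted p = 0.940), with -0.40 ± 0.32 for Col5a1, 0.16 ± 0.34 for Hspg2, 0.15 ± 0.30 for Col4a1 and -0.13 ± 0.32 for Lamb1 (SE). The 10 tested reference genes had a median of -0.12 (camera adjusted p = 0.792), with -0.18 ± 0.24 for Gapdh, 0.42 ± 0.23 for B2m and -0.39 ± 0.35 for Hprt (SE).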

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

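The fits without records under 200 nt, on genes with 1 listed transcript and per transcript were chosen after the results were seen. The cholesterol synthesis and fatty acid lists kept direction and camera call at the preset correlation under all 13 alternatives run (medians -0.80 to -0.70 and -0.53 to -0.42), and with an estimated correlation 0 lists were called under the 12 alternatives run with it. With an estimated correlation, camera also missed a simulated shift of -0.8 with independent noise, so its 0 calls exclude no shift of that size. Where the median of all genes was subtracted, the camera p was carried over from the main fit, so that call could not change. The 2 genes called by limma were 0 without records under 200 nt (510 with an unadjusted p under 0.05) and 0 per transcript (517), since both calls are such records in the first case, while the cause in the second was not tested. Leaving out 1 library, with the lone library assumed to vary like the other group, gave 3 to 16 genes. Of lists, 5 were called, 2 with a mean of at least 5, and 2 to 6 without 1 library. The deviations of same-numbered libraries from their group means correlated at 0.139. With 2 libraries per group both pairs give this same value by construction, so it neither establishes nor excludes pairing. The replicate block gave 2 genes, and 639 with an unadjusted p under 0.05 (limma), where the unpaired fit gave 475. Grouping control library 1 with PROM1 library 1 against the other 2 was tried after the results were seen. This sets the libraries of number 1 against those of number 2. It gave 4 limma calls and 791 genes with an unadjusted p under 0.05, more than the 2 and 475 of the real grouping. Control library 1 grouped with PROM1 library 2 gave 0 limma calls and 222 such genes. More genes thus differed at that level by library number than by group. Under the block the Smad target list was called (adjusted p = 0.0491). No scaling moved the median of all genes by over 0.1. List medians that reversed, all of lists not called, were -0.0261 for cholesterol efflux and -0.17 for proliferation with no filter, -0.13 for cholesterol efflux and 0.0123 for axon guidance with a mean of at least 5, and for sensory neuron identity 0.0103 after rescaling, 0.00043 with no filter, 0.00023 and 0.00032 with pseudocounts of 0.1 and 0.5, and, by construction, 0.0186 after the median of all genes (-0.0286) was subtracted from every gene. Without 1 library, list medians that crossed 0 ran from -0.33 to 0.11 (cholesterol efflux), -0.15 to 0.66 (Smad targets), -0.0476 to 0.0627 (sensory neuron identity), -0.59 to 0.26 (erythroid), -0.29 to 0.37 (proliferation), -0.18 to 0.40 (interferon), -0.31 to 0.0423 (glycolysis and hypoxia), -0.42 to 0.0174 (oxidative phosphorylation), -0.0722 to 0.0177 (axon guidance), -0.10 to 0.19 (extracellular matrix), -0.24 to 0.10 (synaptic vesicle) and -0.24 to 0.0014 (reference genes). Log2 changes of genes not called that crossed 0 ran from -0.83 to 1.23 (Pmvk), -0.72 to 0.12 (Ebp), -0.34 to 1.35 (Apoe), -0.32 to 0.72 (Abcg1), -0.59 to 0.18 (Pmepa1), -0.50 to 0.18 (Gjc3), -0.63 to 0.33 (S100b), -0.13 to 0.46 (Fbln1), -0.46 to 0.0400 (Hba-a1), -0.96 to 0.58 (Hbb-y), -0.26 to 0.37 (Tyms), -0.26 to 0.56 (Isg15), -0.11 to 0.89 (Oasl2), -1.73 to 0.83 (Eno1), -0.99 to 0.0623 (Sdhb), -0.0267 to 0.74 (Efnb2), -0.0502 to 0.36 (Col4a1), -0.35 to 0.0793 (Lamb1), -0.75 to 0.21 (Vamp2) and -0.42 to 0.0651 (Gapdh). The cause of these reversals was not tested. A further 48 of the 108 genes followed moved by over 1.5 times without crossing 0, as did the list medians of regeneration (-0.12 to -0.0258) and of endoplasmic reticulum stress (-0.22 to -0.0452). The immediate early and fibroblast lists had too few genes for a value with a mean of at least 5, and the fibroblast list without PROM1 library 2. Alternatives for read counts and for tables with group values alone did not apply. The depth is unknown, so what it limits was not estimated.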

Other observations

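The tests of explanations, the p53 list with its fits and the regrouping of the libraries were chosen after the results they bear on had been seen, while the fits of the cholesterol list without each library and the pseudocount of 0.1 were planned. Beyond the fixed lists, genes commonly listed as targets of the transcription factor p53 stood high in PROM1 cultures. Phlda3, an inhibitor of Akt, had 40.0 and 37.0 FPKM in the control libraries against 105.6 and 81.8 FPKM in the PROM1 libraries, and Gtse1, a p53-binding cell cycle protein, had 7.31 and 7.84 against 19.8 and 19.4 FPKM. Pidd1, described above, was the third such gene among the lowest p-values. A p53 list was therefore written, and its 18 tested members other than these 3 were examined: 16 were higher and 2 lower, and 12 had both PROM1 libraries above both control libraries. Plk2, a polo-like kinase, had a log2 change of 0.94 ± 0.23, the DNA polymerase gene Polk 1.10 ± 0.30, the death receptor gene Tnfrsf10b 1.07 ± 0.32, Sesn2 0.78 ± 0.28 and the cyclin gene Ccng1 0.48 ± 0.21 (SE). Mdm2, a p53 target and inhibitor, had -0.20 ± 0.35 and Rrm2b -0.45 ± 0.36 (SE). Of the 18 genes, 2 also belong to the fixed lists. A further 2 members of the p53 list were not tested.

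Other genes with low p-values were not called by limma (adjusted p of 0.713 or more) and are named because of their values. The proteoglycan gene Bgn had 1.76 and 1.43 FPKM in the control libraries against 6.26 and 6.90 FPKM in the PROM1 libraries. The small GTPase gene Rasl11a had 5.38 and 5.28 against 14.0 and 18.0 FPKM, the adaptor gene Sh2b3 15.1 and 18.3 against 34.0 and 37.9 FPKM, and the copine gene Cpne6 17.2 and 14.5 against 39.0 and 32.5 FPKM. Prlr had 8.34 and 10.3 against 1.25 and 1.16 FPKM, and Hacd3, an enzyme of very long chain fatty acid elongation, 17.6 and 18.5 against 8.42 and 7.70 FPKM.

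The p53 pattern is a hypothesis with open alternatives. The median of the 18 members was 0.47, above all of the 10000 random lists matched on level (percentile 100), and it lay between 0.38 and 0.63 without each library in turn. Camera gave a p of 1.1e-08 at the preset correlation but p = 0.106 with an estimated correlation (0.224), and fry gave p = 0.0654. Random lists matched on level do not allow for members that vary together. The rank therefore does not decide whether there was a p53 response in the PROM1 cultures, and the tests leave it open. Reads moved between isoforms stay open: the 16 members with 1 listed transcript had a median of 0.473, but their other isoforms may be unlisted. A response to the virus rather than to PROM1 cannot be told apart from one to PROM1, since the viruses differ with the groups, and the interferon list (median 0.341 over 4 low genes) does not decide it. The cell mixture was not tested as a source of the p53 pattern.

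For the lower cholesterol synthesis genes, the tables argue against a difference in scaling, since the median of all tested genes was -0.0286 while the list median was -0.76. They also argue against 1 library alone as the source, since the highest median without a library was -0.701. Fewer glial cells in the PROM1 cultures could account for a part of it. The 3 glial markers with a mean of at least 5 FPKM (Pmp22, Mbp and S100b) had a median of -0.195, higher than the list. Over all 5 tested markers without control library 1 it was -0.36. An exact two-sided permutation of the members of both lists gave p = 0.154. This p reflects spread among genes and not how glial content varied between cultures, so it cannot decide the question, which stays open. An effect of PROM1 on the neurons is the biological explanation that the design names, and it was not tested apart from the cell mixture. For this list too, a response to the virus cannot be told apart from one to PROM1, since the viruses differ with the groups. When the 4 libraries were grouped in the other 2 possible ways, the size of the list median was 0.0366 and 0.0256, and 3 groupings are too few for a share under 0.05.

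The calls on Mir6945 and Mir3470b may come from unstable FPKM of records shorter than a library fragment. RNA over 200 nt was taken for the libraries, while their RefSeq spans are 68 and 126 nt, and the median residual SD of the 54 tested records under 200 nt was 3.49 on the log2 scale against 0.264 for longer ones, a ratio of 13.2. With log2(FPKM + 0.1) a further such record, Mir212 with a span of 91 nt, was called as higher. No biological explanation was tested.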
